A study of Homo sapiens with 8 samples.

How the data were processed

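Ribosome profiling (Ribo-seq, which sequences the mRNA fragments covered by ribosomes, called footprints) and RNA-seq were carried out on HEK293 cells, an established human embryonic kidney cell line, either unmodified (named naive in the labels) or lacking mitochondrial initiation factor 3 (IF-3mt, encoded by the nuclear gene MTIF3). Per the labels' protocols, cells were lysed in the presence of cycloheximide, which stops cytosolic ribosomes, and chloramphenicol, which stops mitochondrial ribosomes. The footprint libraries were made with Ribo-FilterOut and depletion of ribosomal RNA, and the RNA-seq libraries with the SEQuoia Express kit. There were 8 libraries in 4 groups of 2, one group for each assay and genotype, and each library was taken from its own files. The labels do not say whether the replicates of a group were separate cultures, so p-values measure the spread between these libraries, which can be technical in part.

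The authors deposited raw counts, with no normalization, in a pair of tables for each library. One table held 227264 transcript IDs with the number of codons counted and a count, and the other held 13 mitochondrial open reading frames (ORFs). CASAVA 1.8, STAR 2.7.0a and the hg38 build are named in the submitters' processing notes; the counting tool, the transcript annotation, the read filters and the position within a footprint that was counted are not given in the sources used here. In the deposited tables the counted length of a mitochondrial ORF in Ribo-seq equalled its coding length, less the codons of the overlaps MT-ATP8/MT-ATP6 and MT-ND4L/MT-ND4. In RNA-seq it was 10 codons shorter. MT-CO3, whose first position (9207) is also the last of MT-ATP6, had 0 codons left out in Ribo-seq. The codons left out for overlap numbered 16 in each of MT-ATP8 and MT-ATP6 and 3 in each of MT-ND4L and MT-ND4. These numbers equal the codons of the overlaps, which hold the start codons of MT-ATP6 and MT-ND4 and the ends of MT-ATP8 and MT-ND4L. Counts by position within an ORF were not used here. Of the transcript rows, 126981 had no coding length and a count of 0 in every library. Of the 100283 coding rows, 94544 had a count in at least 1 library.

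Isoforms of one gene had separate rows that share reads, and the transcript IDs could not be paired with gene symbols from the tables used here (0 rows matched). Rows with identical counts in all 8 libraries were merged, which left 76611 distinct nuclear rows, and these are called transcripts in the text. Totals over these rows count a read once for each isoform with its own row and are no read numbers. A gene therefore enters as often as it has distinguishable isoforms, and counts of transcripts are not counts of genes. The planned tests of gene lists, the planned check of MTIF3 itself, and the planned choice of one row per gene could not be run for the same reason. The planned naming of genes was reduced to the transcript with the largest rise and the one with the largest fall in mRNA and in footprints, among those past the threshold with a mean of at least 5 CPM in the higher genotype and no overlap between the genotypes. Mitochondrial ORFs were all named. Their positions came from the RefSeq annotation of GRCh38.p14, the assembly that hg38 denotes apart from patches, and their start codons from textbook knowledge.

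Changes were tested with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood F tests, with TMM scaling, the filterByExpr filter (minimum count 10) and Benjamini-Hochberg adjustment at 0.05. The mRNA comparison used the 4 RNA-seq libraries and the footprint comparison the 4 Ribo-seq libraries. Translation efficiency, the number of footprints relative to mRNA, was tested as the interaction of assay and genotype in one model over all 8 libraries, with TMM scaling within each assay. Mitochondrial ORFs were added to the same models and their p-values adjusted over the 13 ORFs alone. Each ORF was measured on 2 scales. On the first, counts were scaled by the library sizes of the nuclear transcripts. On the second, they were scaled by the sum of the 13 ORFs in the library, so that a value is a share of mitochondrial counts and a fall of one ORF raises the others. Values in the text are on the first scale unless the share is named. Log2 changes are given as KO minus naive with the standard error of the model. The model test on the sum of the 13 ORFs was added after the data were examined, as were ratios between the ORFs of one mRNA. Start codon classes and internal starts were compared by exact 2-sided permutation of ORFs, planned before the data were examined. ORFs are not independent replicates of one another. With 2 libraries against 2, an exact permutation of libraries cannot give a p below 0.33, so that all p-values for single ORFs and transcripts rest on the spread that edgeR shares across transcripts. That spread was small, with a coefficient of variation beyond counting noise of 2.17% in RNA-seq and 3.53% in Ribo-seq. These values describe all rows of an assay, nearly all nuclear, and some mitochondrial ORFs varied more. MT-ND4 mRNA was at 622 ± 82.2 CPM in KO and 437 ± 0.225 CPM in naive libraries (mean ± SD, n = 2). Standard errors and p-values of such ORFs can thus be too small. With the mitochondrial rows fitted alone, adjusted p (edgeR) in mRNA was 0.0166 for MT-ND4 and 0.00261 for MT-ATP6, against 1.23e-18 and 2.63e-35.

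The procedure was tested on simulated counts drawn from the real means and library sizes, with one spread for all transcripts of an assay and 200 transcripts changed by known folds. Of 50 transcripts changed by 2-fold, the edgeR test recovered 38 in the mRNA comparison of 59474 transcripts, 49 in the footprint comparison of 67421, and 42 in the translation efficiency comparison of 58445. Of 50 transcripts changed by 1.2-fold it recovered 14, 13 and 1. Calls on transcripts that had not been changed made up 5.76%, 5.63% and 4.62% of all calls. DESeq2 recovered 30, 47 and 35 of the 2-fold changes, and made 0 calls on transcripts that had not been changed. A simulated 4-fold fall of MT-ATP6, which is -2 on the log2 scale, was estimated as -1.98, -1.96 and -2.07, and 0 other mitochondrial ORFs were called by either tool. The simulated mitochondrial ORFs were given the spread of the nuclear transcripts, and all rows were drawn independently. The simulation therefore does not test false calls among real mitochondrial ORFs, some of which varied more, or among rows that share reads. With only 200 changed transcripts, adjustment was also stricter than where many transcripts pass, so recovery in such comparisons can be higher.

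Alternatives were DESeq2 1.42.0, its size factors in place of TMM, no filter on low counts, the replicate number as a covariate, each library left out in turn, all libraries in one fit, TMM over all 8 libraries, mitochondrial rows fitted alone and TMM over the mitochondrial rows. With a library left out, its group has a single library and the spread comes from the other groups. Calls gained in such a fit can therefore reflect a spread set too low. Counting all coding rows without merging, or keeping one row per cluster of neighbouring rows with parallel profiles (within 100 rows, log2 range at most 0.5), was added after the data were examined. Replicates of each group were compared before averaging and differed by more than sampling noise over nuclear rows in all 4 groups, so each counts as a library of its own. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.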

Results

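Footprints and mRNA were counted in naive and IF-3mt KO HEK293 cells, with 2 libraries for each assay and genotype. IF-3mt is the mitochondrial counterpart of bacterial initiation factor 3, which takes part in start site selection on the small ribosomal subunit. The title of the series names initiator tRNA, start codon and leaderless mRNA, the last being the kind of mRNA that begins at or close to its first codon, as most mammalian mitochondrial mRNAs do. Counts over distinct nuclear transcripts summed to between 24029676 and 28970823 per RNA-seq library and between 40629306 and 81028752 per Ribo-seq library. The 13 mitochondrial ORFs held between 157989 and 214879 counts in RNA-seq and between 52141 and 107397 in Ribo-seq. The lowest mitochondrial count of any library was 184, for MT-ATP8 footprints in Ribo_KO replicate 2.

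The first comparison asked how loss of IF-3mt changed the levels of the mitochondrial mRNAs. The mRNA that carries MT-ATP8 and MT-ATP6, the mitochondrially encoded subunits of ATP synthase, fell: MT-ATP6 changed by -1.05 ± 0.04 (log2, SE, 2 libraries per genotype), which is 2.07-fold lower, and MT-ATP8 by -0.80 ± 0.04. MT-CO3, a cytochrome c oxidase subunit encoded directly downstream of MT-ATP6, fell by 0.56 on the log2 scale, and MT-ND3, a complex I subunit, by 0.88. Complex I mRNAs otherwise mostly rose. MT-ND4L and MT-ND4, which share one mRNA, rose by 0.69 ± 0.04 and 0.51 ± 0.04, MT-ND2 by 0.45 ± 0.04, and MT-ND1 and MT-ND6 each by 0.26 ± 0.04. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 11 of the 13 ORFs passed the threshold, 5 higher and 6 lower in the KO. As shares of mitochondrial counts, 5 rose and 5 fell. MT-CO1, the catalytic subunit of cytochrome c oxidase, differed by -0.06 ± 0.04 and MT-CYB, the cytochrome b subunit of complex III, by -0.02 ± 0.04, and neither passed. As shares they were at 0.03 and 0.07 and did not pass either, but MT-CO1 did without RNA_naive replicate 2 (0.05), and MT-CYB in 4 of 8 alternatives, among them leaving out RNA_naive replicate 2 (0.10) or RNA_KO replicate 1 (0.10) and TMM over the mitochondrial ORFs (0.09). MT-CO2 (-0.16 ± 0.04) and MT-ND5 (-0.18 ± 0.04) also passed, but not in every alternative. MT-CO2 did not pass with the mitochondrial rows fitted alone and was at adjusted p = 0.0891 (edgeR) as a share, which passed without RNA_naive replicate 2 (-0.11) or RNA_KO replicate 2 (-0.13), and MT-ND5 changed by -0.06 without RNA_KO replicate 2 (adjusted p = 0.280 in edgeR). MT-ND5 also did not pass with DESeq2 or with the mitochondrial rows fitted alone, both at -0.18, and as a share (-0.09) it did not pass in 4 of 8 alternatives. Relative to nuclear transcripts MT-CO1 passed without RNA_naive replicate 1 (-0.09) or RNA_KO replicate 1 (-0.15). Without RNA_KO replicate 2 it was at 0.03 and did not pass.

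Footprints were compared in the same way, to ask which ORFs held fewer or more ribosomes. MT-ATP6 fell the most of the 13 ORFs, by -2.59 ± 0.06 or 6.01-fold (adjusted p = 9.07e-32, edgeR), from 68.3 ± 2.33 CPM (counts scaled to the nuclear library size) in naive cells to 11.3 ± 0.0877 in KO cells (mean ± SD, n = 2 each). MT-ND4 fell by -1.06 ± 0.05, or 2.08-fold, from 54.6 ± 1.82 to 26.3 ± 0.860 CPM, although its mRNA had risen. MT-ATP8 changed by -1.01 ± 0.09, MT-CO2 by -0.71 ± 0.06, MT-CO3 by -0.66 ± 0.07, MT-ND1 by -0.55 ± 0.05 and MT-ND3 by -0.41 ± 0.07. The fall of MT-ND3 depended on the scale: as a share it was at -0.06 and did not pass (adjusted p = 0.387, edgeR), but did in 1 of 8 alternatives. MT-ND2 rose by 0.47 ± 0.05. All 13 ORFs passed the threshold on this scale, 3 higher and 10 lower, against 9 to 13 in the alternatives, with 9 (1 higher, 8 lower) for the mitochondrial rows fitted alone. As shares of mitochondrial footprints 5 rose and 6 fell, against 3 higher and 7 lower with TMM over the mitochondrial ORFs. The remaining changes were small and depended on the scale or on single libraries. MT-CO1, MT-CYB and MT-ND5 were lower relative to nuclear transcripts (-0.20 ± 0.10, -0.16 ± 0.07 and -0.18 ± 0.07) but higher as shares (0.16, 0.20 and 0.18), at 0.07, 0.11 and 0.09 and not past the threshold with TMM over the mitochondrial ORFs. The share of MT-CO1 did not pass, but did in 4 of 8 alternatives, among them DESeq2 (0.16), the mitochondrial rows fitted alone (0.16) and leaving out Ribo_naive replicate 2 (0.19). On either scale MT-CYB and MT-ND5, and on the first MT-CO1, did not pass without Ribo_KO replicate 1 (-0.15, -0.11 and -0.16 for MT-CO1, MT-CYB and MT-ND5 relative to nuclear transcripts) or without Ribo_KO replicate 2 (-0.25, -0.21 and -0.20); MT-CO1 also failed without Ribo_naive replicate 2 (-0.09). MT-ND4L (0.24 ± 0.06) did not pass in 2 of 9 alternatives, among them the mitochondrial rows fitted alone, and was at 0.10 without Ribo_naive replicate 1. MT-ND6 (0.12 ± 0.06) failed without Ribo_naive replicate 1 (0.08), Ribo_naive replicate 2 (0.14) or Ribo_KO replicate 2 (0.08), and also with DESeq2, the mitochondrial rows fitted alone or one row per cluster. MT-ND4L and MT-ND6 rose as shares, by 0.59 and 0.46. MT-ND1 fell as a share by 0.20, and was at -0.11 without Ribo_naive replicate 1 (adjusted p = 0.0999, edgeR).

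**Figure D1:**
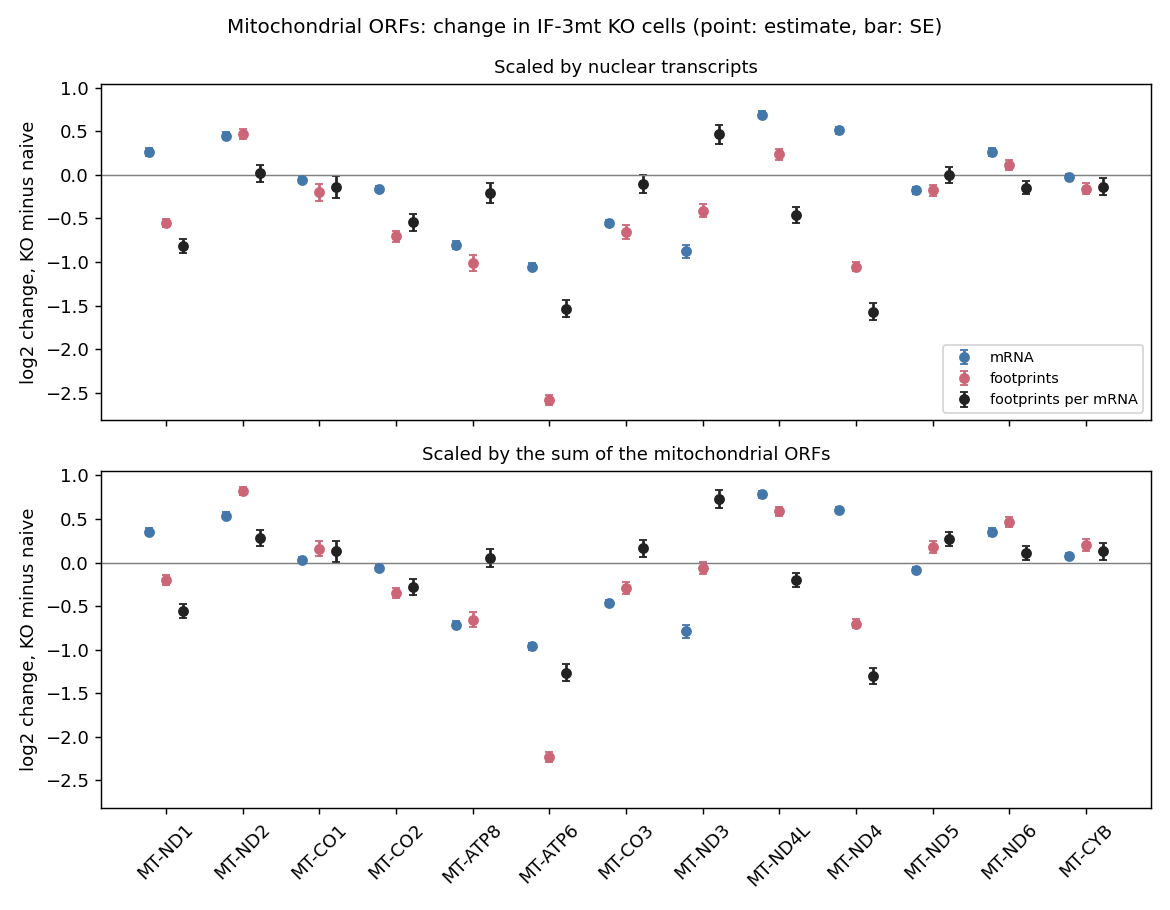
Log2 change, KO minus naive, of mRNA (blue), footprints (red) and footprints per mRNA (black) for the 13 mitochondrial ORFs in genome order; points are edgeR estimates and bars their standard errors. The upper panel is scaled by nuclear transcripts and the lower by the sum of the 13 ORFs. MT-ATP6 and MT-ND4 have the largest falls in footprints per mRNA in both panels (-1.53 and -1.57 in the upper, -1.26 and -1.30 in the lower).

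Translation efficiency, here footprints per mRNA in one model over all 8 libraries, fell furthest for MT-ND4 and MT-ATP6. MT-ND4 changed by -1.57 ± 0.10, or 2.97-fold lower (adjusted p = 6.4e-22), and MT-ATP6 by -1.53 ± 0.10, or 2.90-fold lower (adjusted p = 7.44e-22, both edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 13 ORFs). Of 58607 nuclear transcripts, 8 had a lower value than MT-ND4 and were past the threshold, and 9 had a lower value than MT-ATP6. MT-ND1 fell by -0.82 ± 0.08, MT-CO2 by -0.55 ± 0.09 and MT-ND4L by -0.46 ± 0.09. MT-ND3 rose by 0.47 ± 0.11. MT-ND3 footprints themselves fell (-0.41), but less than its mRNA (-0.88). MT-ND4L footprints themselves rose (0.24), but less than its mRNA (0.69). The other 7 ORFs did not pass; MT-ATP8, which shares its mRNA with MT-ATP6, was at -0.21 ± 0.11 with a 95% interval from -0.43 to 0.02. As shares, 8 ORFs passed: MT-ND2 (0.28), MT-ND3 (0.73) and MT-ND5 (0.27) rose, and MT-ATP6 (-1.26), MT-ND4 (-1.30), MT-ND1 (-0.56), MT-CO2 (-0.28) and MT-ND4L (-0.20) fell. By complex, complex I had 1 ORF higher and 3 lower of 7 relative to nuclear transcripts and 3 higher and 3 lower as shares, while complex IV had 1 lower of 3 on both scales. Without Ribo_naive replicate 1 the number of ORFs past the threshold relative to nuclear transcripts went from 6 to 10, with MT-CO1 (-0.25), MT-ATP8 (-0.39), MT-CO3 (-0.19) and MT-CYB (-0.15) added; MT-ATP8 also passed without RNA_naive replicate 1 (-0.26) or RNA_KO replicate 2 (-0.30). As shares, MT-ND4L failed in 7 of 12 alternatives, namely with DESeq2 (-0.20), with the mitochondrial rows fitted alone (-0.20) and without Ribo_naive replicate 2 (-0.16), Ribo_KO replicate 1 (-0.18), RNA_naive replicate 1 (-0.21), RNA_naive replicate 2 (-0.19) or RNA_KO replicate 1 (-0.17), MT-CO2 without RNA_naive replicate 2 (-0.24) or RNA_KO replicate 2 (-0.22), and MT-ND2 without RNA_naive replicate 1 (0.24); with TMM over the mitochondrial ORFs, MT-ND2 (0.17) and MT-ND5 (0.16) failed, which left 1 ORF higher and 5 lower. MT-CO3 did not pass as a share (0.16) but did in 4 of 12 alternatives, with DESeq2 (0.16), with the mitochondrial rows fitted alone (0.16) and without Ribo_naive replicate 1 (0.15) or Ribo_naive replicate 2 (0.17), and so did MT-CO1 with the mitochondrial rows fitted alone (0.13), MT-CYB without Ribo_naive replicate 1 (0.19) and MT-ND6 without RNA_KO replicate 2 (0.19).

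**Figure D2:**
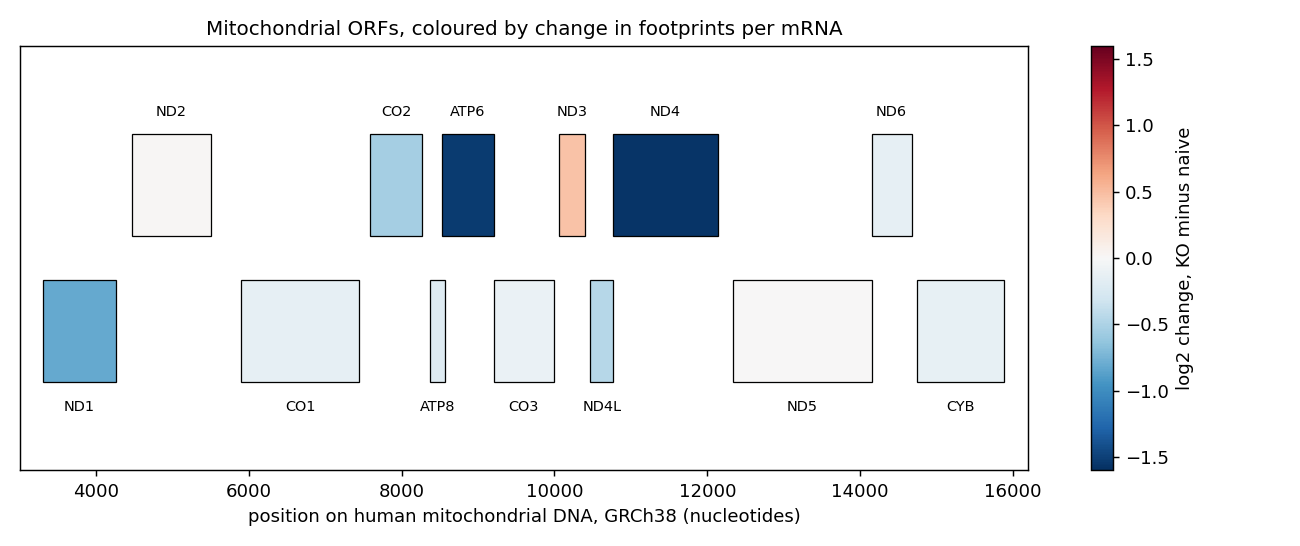
Map of the 13 ORFs on human mitochondrial DNA (GRCh38, positions in nucleotides on the x axis), coloured by the log2 change of footprints per mRNA relative to nuclear transcripts; ORFs alternate between rows for legibility only. The darkest blue boxes are MT-ATP6 (8527 to 9207) and MT-ND4 (10760 to 12137), each the downstream ORF of a pair that shares an mRNA.

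The ORFs that do not begin near the 5' end of an mRNA were compared with the others. MT-ATP6 (chromosome MT, 8527 to 9207) starts inside MT-ATP8 (8366 to 8572), with an overlap of 46 nucleotides, and MT-ND4 (10760 to 12137) starts inside MT-ND4L (10470 to 10766), with an overlap of 7 nucleotides. The mean log2 change in translation efficiency was -1.55 ± 0.0240 (SD, n = 2 ORFs) for the internal ORFs and -0.19 ± 0.33 (SD, n = 11 ORFs) for the others, a difference of -1.36 (exact 2-sided permutation p = 0.0128 over 78 splits of the ORFs, the smallest those splits allow; adjusted p = 0.0256 over 2 planned tests). Within a library, scaling cancels from the ratio of downstream to upstream ORF. The MT-ATP6 to MT-ATP8 ratio of footprints per codon went from 2.10 ± 0.244 in naive to 0.717 in KO cells (mean ± SD, n = 2), where the libraries differed by far less than their counting error, while the same ratio of mRNA went from 0.709 ± 0.0210 to 0.595 ± 0.0180. The MT-ND4 to MT-ND4L ratio of footprints went from 0.676 ± 0.0543 to 0.278 ± 0.00689, and of mRNA from 0.783 ± 0.00261 to 0.691 ± 0.0156. Relative to mRNA, the ratios changed by -1.30 ± 0.13 and -1.10 ± 0.09 (log2 ± SE), or 2.46-fold and 2.14-fold.

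**Figure D3:**
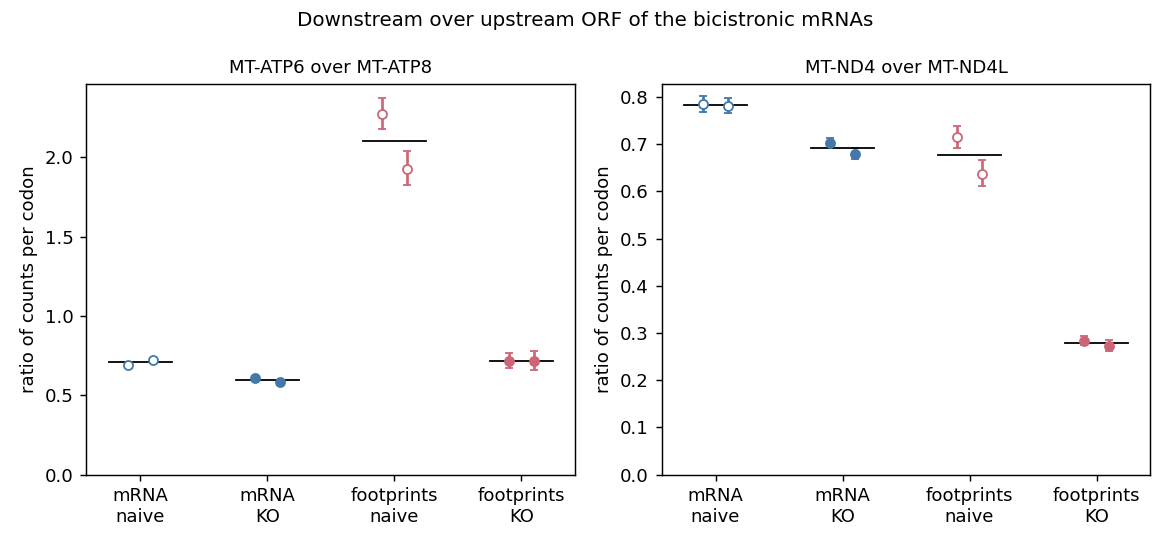
Ratio of counts per codon, downstream over upstream ORF of each bicistronic mRNA, in each library; open points are naive and filled points KO libraries, bars are counting errors (1 SE on the log2 scale) and lines the group means. Footprint ratios (red) fall from 2.10 to 0.717 for MT-ATP6 and from 0.676 to 0.278 for MT-ND4, and mRNA ratios (blue) fall less, from 0.709 to 0.595 and from 0.783 to 0.691.

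Start codon classes did not separate the ORFs in the same way. The 4 ORFs that start with AUA or AUU (MT-ND1, MT-ND2, MT-ND3 and MT-ND5) changed in translation efficiency by a mean of -0.08 ± 0.53 (SD) and the 9 ORFs that start with AUG by -0.54 ± 0.60. The difference of 0.46 did not pass (exact 2-sided permutation p = 0.211 over 715 splits, adjusted p = 0.211 over 2 planned tests). The AUG class includes both internal ORFs, MT-ATP6 (-1.53) and MT-ND4 (-1.57), which lower its mean. The comparison is therefore not separate from that of internal starts. Within the first class MT-ND1 fell by -0.82 ± 0.08 and MT-ND3 rose by 0.47 ± 0.11.

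Total mitochondrial footprints were lower in the KO. The counts of the 13 ORFs equalled 0.139% ± 0.0106 of the scaled nuclear footprint counts in naive and 0.109% ± 0.00464 in KO libraries (mean ± SD, n = 2), and 0.743% ± 0.00935 and 0.696% ± 0.0588 in RNA-seq. In the edgeR model the sum changed by -0.36 ± 0.11 in footprints (adjusted p = 0.00882 over 3 tests) and by -0.09 ± 0.04 in mRNA (adjusted p = 0.0250). The change in footprints was at -0.32 without Ribo_KO replicate 1 and -0.41 without Ribo_KO replicate 2, and that in mRNA at -0.01 without RNA_KO replicate 2 and -0.09 with DESeq2, and these did not pass. Footprints per mRNA for the sum changed by -0.27 ± 0.14 and did not pass (adjusted p = 0.0690, edgeR), but did with DESeq2 (-0.27) and without Ribo_naive replicate 1 (-0.34) or Ribo_naive replicate 2 (-0.18).

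Nuclear transcripts were compared to describe the rest of the transcriptome and the cytosolic translatome, without gene names. In mRNA level 13059 of 59626 tested transcripts (21.9%) passed the threshold in edgeR, 6365 higher and 6694 lower in the KO, with a median change of 1.30-fold in either direction; 1326 were past it and over 2-fold, 920 higher and 406 lower. Isoforms of one gene that share reads are counted separately here. DESeq2 called 4160, and 8662 passed without RNA_KO replicate 1. The largest rise among transcripts of at least 5 CPM was ENST00000356864.3, from 1.02 ± 0.0913 to 5.78 ± 0.615 CPM (log2 change 2.51 ± 0.18). The largest fall was ENST00000275954.4, from 7.12 ± 0.407 CPM in naive libraries to 1 count in the KO libraries together, against 391 counts in the naive libraries, a ratio of 379 with a 95% exact counting interval from 67.6 to 15003.

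In footprints 20690 of 67543 transcripts (30.6%) passed, 10142 higher and 10548 lower, with a median change of 1.27-fold; 2082 were past it and over 2-fold, 1529 higher and 553 lower. DESeq2 called 7921. The largest rise was ENST00000405655.8, from 1.14 ± 0.241 to 6.39 ± 0.0697 CPM (log2 change 2.56 ± 0.12), and ENST00000275954.4 again had the largest fall, from 896 to 8 counts, a ratio of 116 with a 95% exact counting interval from 58.8 to 270.4. Footprint and mRNA changes, which come from separate libraries, went together. Of 58607 transcripts tested in both, 4250 passed in both and were higher, against 970 for independent lists, 4556 passed in both and were lower, against 1119, and 56 passed in opposite directions. Across transcripts, which are not independent replicates, the log2 changes had Pearson's r = 0.749 and Spearman's rho = 0.648.

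**Figure D4:**
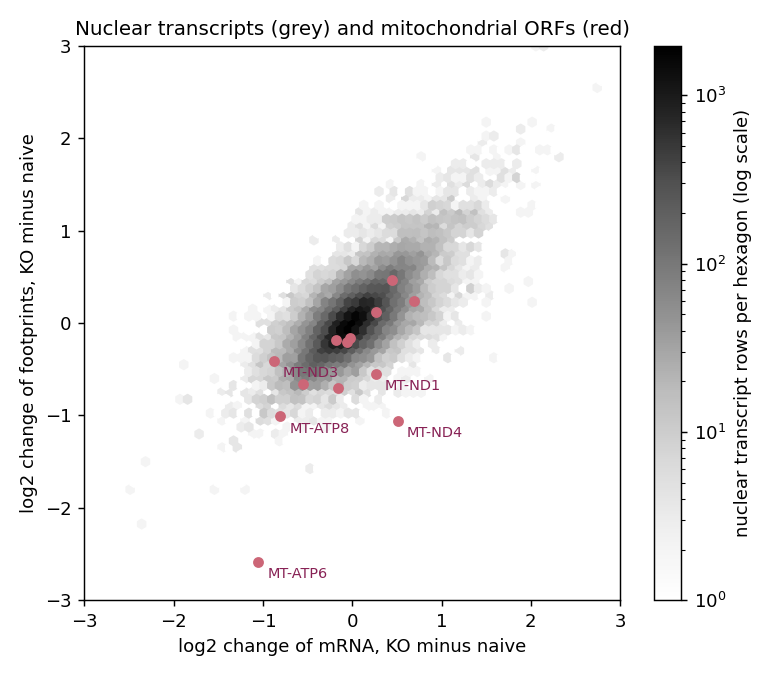
Log2 change of mRNA (x axis) against log2 change of footprints (y axis), KO minus naive, for 58507 nuclear transcripts (grey hexagons, darker for more transcripts on a log scale; 100 further transcripts lie outside the frame) and the 13 mitochondrial ORFs (red). Nuclear transcripts lie along the diagonal (r = 0.749 over all 58607), and MT-ATP6 (-1.05, -2.59) and MT-ND4 (0.51, -1.06) lie below it.

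Fewer nuclear transcripts passed in translation efficiency, a test that recovered 1 of 50 simulated 1.2-fold changes, against 14 of 50 for mRNA and 13 of 50 for footprints. Larger changes were recovered about as well. Of 50 simulated 1.5-fold changes it recovered 31, against 31 for mRNA and 39 for footprints, and of 50 2-fold changes 42, against 38 and 49. In edgeR 210 of 58607 transcripts passed, 105 higher and 105 lower, of which 48 were over 2-fold, and DESeq2 called 43. With TMM over all 8 libraries in place of TMM within assays, 250 passed, 89 higher and 161 lower. The number rested on single libraries: 641 passed without Ribo_naive replicate 1 (196 higher, 445 lower), 308 without Ribo_naive replicate 2 (183 higher, 125 lower), and 68, 87, 82, 108, 92 and 98 without RNA_KO replicate 1, RNA_KO replicate 2, RNA_naive replicate 1, RNA_naive replicate 2, Ribo_KO replicate 1 and Ribo_KO replicate 2. No nuclear transcript is named for this comparison.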

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

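The tests of library scaling by the ratio between ORFs of one mRNA, of a start-codon peak and of isoform rows were chosen after the results were seen, and the comparison of internal starts with other ORFs had been planned, but its bound was written down after its result was seen. The tests on replicate number were written down before their results were seen.

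MT-ND1 and MT-ND4 stood out because their mRNA and footprint changes had opposite directions, past the threshold on both scales, and the interaction of assay and genotype passed as well. MT-ND1 footprints per mRNA changed by -0.82 and MT-ND4 footprints per mRNA by -1.57 (log2). As a share, the fall of MT-ND1 footprints was at -0.11 and did not pass without Ribo_naive replicate 1.

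MT-ATP6 and MT-ND4 had fewer footprints per mRNA in the KO. Library scaling as the cause is argued against by the ratios to the upstream ORF in the same library, which changed relative to mRNA by -1.30 ± 0.13 and -1.10 ± 0.09, beyond 3 standard errors. A start inside a bicistronic mRNA is a candidate explanation: the internal ORFs stood apart from the others at the smallest exact permutation p the ORFs allow, 0.0128, but only 2 such ORFs exist. Loss of a start-codon peak alone would not account for MT-ATP6 if the 16 codons left out are those overlapping MT-ATP8, which hold its start. Their number equals that overlap, but which codons were left out is not given. Footprints by position were not used, so this rests on codon numbers alone. For MT-ND4, where 3 codons are left out, such a loss cannot be told apart from loss along the ORF. The position counted within a footprint is not given in the sources used here. Differences between cell clones other than the knockout also stay open, as untested.

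Many nuclear transcripts passed the threshold in mRNA level and in footprints. With one row per cluster of parallel neighbouring rows, 22.12% of tested transcripts passed in mRNA level, against 21.9%, while the number fell to 4079. Clusters were formed by position and profile, without gene names. Unchanged rows of different genes can thus be merged while changed rows stay, which can hold the percentage up. The comparison therefore cannot decide whether repeated isoform rows raise the share. Replicate number, tested in the same libraries with genotype in the model, called 0 of 59626 transcripts in mRNA level (3243 at an unadjusted p under 0.05, edgeR) and 87 of 67543 in footprints (4563 at an unadjusted p under 0.05), which are 0% and 0.381% of those called by genotype in that model. In that model the spread was thus not far too low for differences between replicates as numbered. The spread between replicates also sets the error of that model, so few calls by replicate number were likely beforehand. The main fit leaves replicate number out, and DESeq2 called 4160 and 7921 transcripts by genotype, against 13059 and 20690 in edgeR. Whether the spread in the main fit is too low is therefore not settled. It also stays open for separate cultures, since the labels do not say what the replicates are. A difference between clones stays open as well.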

How the results depend on the processing

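Alternatives for the sum of the 13 ORFs, the ratios and the row sets were added after the data were examined. Translation efficiency calls for MT-ATP6 (-1.66 to -1.40), MT-ND4 (-1.69 to -1.43), MT-ND1, MT-CO2, MT-ND3 and MT-ND4L relative to nuclear transcripts were the same under all 13 alternatives. The comparison of internal starts kept its call under its 10 alternatives, at -1.43 to -1.29 with one library left out, -1.36 as shares and -1.55 for footprints in place of translation efficiency. Its permutation p was already the smallest possible, so the kept call says little beyond these differences. For footprints MT-ATP6 (-2.59) stood apart, while MT-ND4 (-1.06) was close to MT-ATP8 (-1.01), which does not start internally. With DESeq2 the numbers of nuclear transcripts past the threshold were 4160 in mRNA, 7921 in footprints and 43 in translation efficiency; with one row per cluster they were 4079 of 18437, 6359 of 21337 and 124 of 17995. In translation efficiency the percentage past the threshold rose from 0.358% to 0.689%. Leaving out one library gave 8662 to 10457, 15036 to 18265 and 68 to 641, and 6 to 10 mitochondrial ORFs in translation efficiency relative to nuclear transcripts. For the sum of the 13 ORFs, DESeq2 gave -0.094 in mRNA, not past the threshold, and -0.27 in translation efficiency, past it, the replicate block gave -0.26 in translation efficiency, past it, and leaving out one library gave -0.18 to -0.011 in mRNA, -0.44 to -0.28 in footprints and -0.35 to -0.18 in translation efficiency. The signs of ORFs near 0 turned when single libraries were left out, in mRNA for MT-CYB (-0.075 to 0.027) and MT-CO1 (-0.15 to 0.025), in translation efficiency for MT-ND2 (-0.086 to 0.14) and MT-ND5 (-0.11 to 0.13), and as shares for MT-ATP8 (-0.035 to 0.13). With TMM over the mitochondrial rows MT-ATP8 was at -0.053 and MT-ND6 at -4.2e-05 in translation efficiency. Over all alternatives, 44 calls on single ORFs were lost and 27 were added, none of them on MT-ATP6 or MT-ND4. The cause of these changes was not tested.

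The replicate numbers gave little sign of pairing the samples. Over 4002 transcripts, replicate differences correlated at 0.18 between Ribo_naive and RNA_naive and at 0.15 between Ribo_naive and Ribo_KO. The other pairs of groups were between -0.01 and 0.01. A weak link between the replicates of these Ribo-seq and RNA-seq groups stays possible. With the replicate block, 13902, 22812 and 212 transcripts passed, and as shares MT-CO1 footprints (0.16) and MT-CYB mRNA (0.07) passed as well. Not run were the gene list tests and the longest row per gene, which need gene symbols. In the simulation, small changes were mostly missed at these depths and 2 libraries per group, which were not varied separately. Of 50 simulated 1.2-fold changes in translation efficiency 1 was recovered. In the data many small changes passed in mRNA and footprints, with median changes of 1.30-fold and 1.27-fold among transcripts past the threshold. MT-ATP8 footprints (184 to 599 counts) are the lowest of the ORFs.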

Other observations

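Naive cells differed widely in footprints per mRNA between mitochondrial ORFs, which no planned comparison covers. Per codon and as shares of the mitochondrial counts of each assay, MT-ND5 was highest at 3.12 and MT-ATP8 lowest at 0.229, a span of 13.6-fold. MT-ND3 was at 2.43, MT-ND1 at 1.49 and MT-CYB at 1.29, against 0.678 for MT-ATP6 and 0.652 for MT-ND4. In KO cells MT-ATP6 was at 0.282 and MT-ND4 at 0.265, near MT-ATP8 at 0.234, and MT-ND3 was highest at 3.99. The counted regions of the assays differ by 10 codons, which weighs most on the shortest ORF, MT-ATP8, with 53 codons in Ribo-seq and 43 in RNA-seq.

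Whether mitochondrial mRNA levels follow ribosome occupancy was tested as a hypothesis, with the bound written down before the result was seen, and the test of scaling was chosen after. Across the 13 ORFs, which are not independent replicates, mRNA change and translation efficiency change had Pearson's r = -0.11 (permutation p = 0.721, 95% interval from -0.62 to 0.47) and Spearman's rho = -0.23 (permutation p = 0.444), and r = -0.42 without MT-ATP6 and MT-ND3, the ORFs farthest from the median mRNA change. The value met the bound set against the hypothesis, an r of 0 or below, but not by more than its interval, which was added after the result was seen and leaves a moderate positive relation possible. The hypothesis stays undecided, and mRNA enters both measures, which pulls r downward. Of the same family of 2 relations, mRNA change and footprint change had r = 0.64 (permutation p = 0.0115, adjusted p = 0.0229) and rho = 0.52 (permutation p = 0.0773), with r = 0.52 without the same ORFs. One scaling factor per library as the cause of the mRNA changes is argued against by the 5 ORFs that rose and the 5 that fell on both scales. A separate effect of genotype on mRNA stability or processing, or a difference between clones, may be involved and was not tested.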
